A study of Homo sapiens with 5 samples.

How the data were processed

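Nascent RNA was profiled by PRO-seq, a precision run-on assay in which engaged RNA polymerases extend their transcripts with biotin-labelled nucleotides, so that the captured reads report transcription in progress rather than accumulated RNA. The samples were 5 libraries of HEK293T, a human embryonic kidney cell line that carries the SV40 large T antigen. Per the labels, the cells were monoclonal lines with a landing pad, a genomic site built to accept inserted DNA, holding either the PGK promoter (2 libraries) or the CAG promoter (3 libraries). Groups and replicate numbers were taken from the sample titles. All 5 columns of the deposited table were matched to a sample by its description, and 0 columns were left unmatched.

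The deposited values are raw counts per Ensembl gene identifier: whole numbers whose sum differed between libraries. Per the submitters' processing notes, fastp 0.23.2, cutadapt, Bowtie2 2.5.1, HISAT2 2.2.1, UMI-tools and featureCounts 2.0.3 were used with the hg19 build. The labels' protocol places random bases in both adapters. The role of each tool, the annotation, the strand setting and the part of each gene that was counted are not given in the sources used here. Whether reads of overlapping genes, antisense partners or near-identical copies were kept apart is therefore not known here, and values of such genes are uncertain. The table has 1 value per gene and library, so promoter-proximal and gene-body signal were not distinguished.

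The table held 20019 rows, of which 18 carried no identifier. Those 18 rows were left out of library sizes and tests. They held 13 to 25 counts per library, at most 0.000448% of a library. Gene names were not paired with identifiers in the table, and the reference table used here (assembly GRCh38.p14) held 0 rows with an Ensembl identifier. Genes are therefore given by identifier. The 35 gene lists fixed before the data were examined, the tests of chromosomes, the comparison of PGK1 and ACTB and the shares of counts by gene class were not analysed here. RNA-seq of the same lines was not used here, so no RNA stability was computed.

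Library totals were 5582070 and 3712105 counts in the PGK line and 4873883, 5003130 and 5864157 counts in the CAG line. Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15), which left 13400 of 20001 genes and at least 99.8% of each library's counts. Counts were scaled by TMM. The main test was edgeR's quasi-likelihood F test of CAG over PGK with no covariate (edgeR 4.0.16, R 4.3.3). Calls had a Benjamini-Hochberg adjusted p under 0.05. A standard error was computed as the size of the log2 fold change over the square root of F. For large changes that rest on few counts in a line, this value is smaller than counting error allows. It is therefore not printed for single genes of that kind. Levels are CPM, counts relative to the TMM-scaled library size, and log2 CPM used a prior count of 2. Limits for a count of 0 used 3 counts over all libraries of a line and cover counting error only.

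Named genes followed a rule fixed before the data were examined. In each direction it took the 12 genes with the largest change among called genes with a mean of at least 5 CPM over the 5 libraries whose CAG and PGK libraries did not overlap. Because the files do not pair identifiers with names, only the 2 leading genes per direction are printed and the other 10 are summarised, as are the 10 genes with the highest mean CPM, which the rule also took. For genes with 0 counts in a line, the fitted fold change that orders them depends on the prior count. Where such a gene is printed singly, a lower limit is given in its place. The parts of the rule that needed gene names were not run.

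Stretches of consecutive rows were described after the data were examined. The log2 fold changes of the tested genes were taken in the row order of the table, centred on their median and limited to a size of 1. They were then divided into stretches of at least 20 genes by least-squares optimal partitioning, with a penalty per boundary of 4 times the noise variance times the natural log of the number of genes. A stretch was called shifted when the median of its log2 fold changes lay more than 0.2 from the median of all tested genes. The sources used here do not say what the row order is. Of neighbouring tested rows, 52.0% rose in identifier number, so the rows were not sorted by identifier. Stretches were also found from 1 library per line and their levels read in the libraries left out.

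Alternatives were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0, limma-trend (limma 3.58.1), no filter, a minimum of 1 CPM in every library, the replicate number as a block, glmTreat against a log2 fold change of 0.5 and leaving out each library. DESeq2 was run on all genes with a count and, added later, on the 13400 genes tested by edgeR. The tests were tried on simulated counts for the 13400 genes of this comparison with 200 genes changed. edgeR recovered 20.0% of genes changed 1.25-fold, 66.0% at 1.5-fold, 96.0% at 2-fold and 100% at 4-fold, and 4.08% of its calls were false. These rates come from a single draw with independent genes and the same dispersion in both lines. Far fewer genes were changed than were called in the data, so the rates do not carry over to those calls. In shuffled data, planted stretches of 100 genes were recovered in 100% of 10 trials at a log2 shift of 0.4 in 70.0% at 0.3 and in 10.0% at 0.2. For 50 genes the share was 60.0% at 0.4 and 0% at 0.3 and 0.2, and for 300 genes it was 50.0% at 0.2. A planted stretch counted as recovered only where the stretch found matched it closely in place and length. Stretches planted at 0.2, the threshold itself, were thus often missed, in part because noise can place their median under it. Shifts between 0.2 and 0.3 were not tried. Partitioning and exact permutation tests used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.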

Results

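Nascent transcription was compared between monoclonal HEK293T landing-pad cells with the PGK promoter, from a housekeeping gene of glycolysis (2 libraries), and with the CAG promoter, a strong synthetic promoter (3 libraries). The series was made to measure RNA stability together with RNA-seq from the same cells, and the comparison of lines here shows how alike their nascent transcription was. Library totals ranged from 3712105 counts in PGK replicate 2 to 5864157 counts in CAG replicate 3. Between 15205 and 16234 of 20001 genes had at least 1 count in a library, and 2715 genes had 0 counts in every library. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. They also do not say how many clones stand behind each promoter, called a line here, so effects of the promoter and of the clone were not separated.

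Nascent counts were spread over many genes. In the 13400 tested genes, the 2170 highest held 50% of the mean CPM, and the median gene had 47.5 CPM. The 10 highest genes took 1.5% ± 0.0402 of counts in the PGK line (SD, n = 2) and 1.37% ± 0.131 in the CAG line (SD, n = 3). An exact two-sided permutation test of these shares gave p = 0.4, and 2 against 3 libraries cannot go below 0.2. The share in CAG replicate 2 lay above that in PGK replicate 1. Of those 10 genes, 3 were called higher and 7 lower in the CAG line. The gene with the highest mean stood at 1047 ± 58.0 CPM in the PGK line (n = 2) and 2871 ± 93.5 CPM in the CAG line (n = 3), a 2.74-fold rise with an edgeR adjusted p of 1.99e-14.

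Libraries of one line resembled each other more than libraries of different lines. Across the tested genes, Spearman's rho was 0.993 for the PGK pair and 0.996 for each of the 3 CAG pairs. Across lines it lay between 0.964 and 0.968. Genes are not independent replicates, so these values describe the libraries only. The SD of the log2 difference between libraries was 0.329 in the PGK pair, 0.224 to 0.233 in the CAG pairs and 0.598 to 0.661 across lines. No pair was a repeat of one library: chi-square per degree of freedom was 1.63 to 1.83 in the CAG pairs and 4.47 in the PGK pair, where sampling noise alone gives about 1. The PGK replicates thus differed from each other by more than the CAG replicates did.

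Many genes differed between the lines, most of them by a small amount. Of 13400 tested genes, 5818 were called by edgeR's quasi-likelihood test at an adjusted p under 0.05, which is 43.4% of them. In the CAG line 3046 genes were higher and 2772 lower, and without PGK replicate 1 the balance turned, with 2812 higher and 2877 lower. The size of the change was under 2-fold for 4886 of the called genes (84.0%), and the median size was 0.50 on the log2 scale. Larger changes were more often rises in the CAG line: 672 genes were at least 2-fold higher and 260 at least 2-fold lower. At 4-fold the counts were 140 higher and 68 lower, and at 8-fold 55 higher and 33 lower. The CAG libraries did not overlap the PGK libraries for 61.2% of all tested genes, where chance gives 20.0%.

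**Figure D1:**
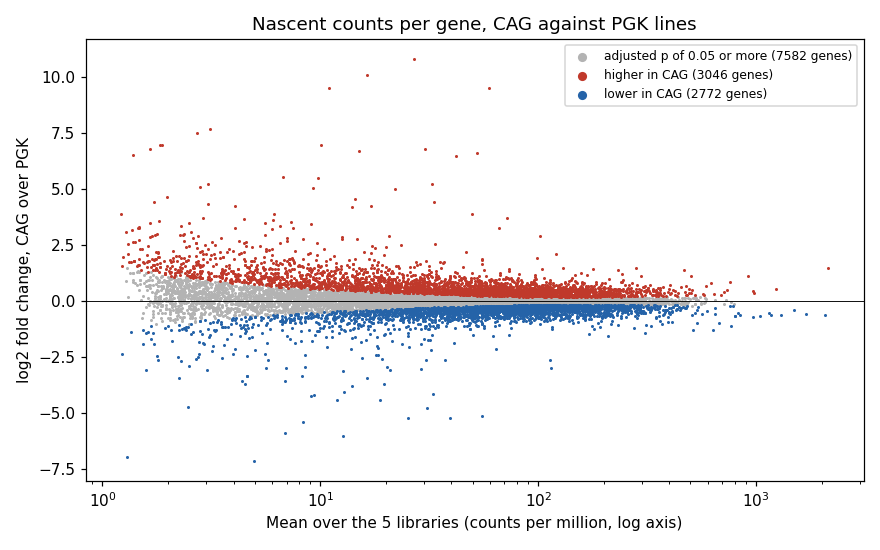
Each point is 1 of 13400 tested genes, with its mean over the 5 libraries in CPM on a log axis and its log2 fold change, CAG over PGK. Red points are the 3046 genes called higher and blue points the 2772 called lower at an edgeR adjusted p under 0.05; the largest changes on both sides exceed 4-fold and more of them lie above 0 than below.

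Calls were more frequent among genes with higher counts. Genes were divided by mean level into 4 groups of equal size. In the group with the lowest levels (median 6.70 CPM), 35.9% were called, with a median standard error of 0.26 on the log2 scale. In the group with the highest levels (median 157 CPM), 49.7% were called, and the median standard error was 0.07. Fold changes of scarce genes were thus measured less precisely at this depth. When the test was made against a log2 fold change of 0.5 instead of 0 (edgeR's glmTreat), 1145 genes passed, 714 higher and 431 lower. DESeq2 on all genes with a count called 3943 genes, 2099 higher and 1844 lower, and on the 13400 genes tested by edgeR it called 4054, 2201 higher and 1853 lower.

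The 2 genes with the largest fitted rises were counted in every CAG library and in neither PGK library. ENSG00000127399 had 231, 233 and 248 counts in the CAG libraries (45.1 ± 2.54 CPM, SD, n = 3) and 0 counts in both PGK libraries. Against the limit of 3 counts over the PGK line it was at least 138-fold higher in the CAG line, with an edgeR adjusted p of 1.18e-15. ENSG00000170627 had 132, 136 and 163 counts in the CAG libraries (27.2 ± 0.498 CPM, n = 3) and 0 in both PGK libraries. It was at least 83.4-fold higher in the CAG line (edgeR adjusted p = 1.27e-13). The other 10 leading rises had fitted sizes between 5.21 and 9.53 on the log2 scale and adjusted p of at most 1.63e-09 in edgeR. Fitted sizes depend on the prior count where the PGK count is 0, so the order of the leading rises is not settled.

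The 2 genes with the largest falls had a few counts left in the CAG line. ENSG00000185070 had 179 and 108 counts in the PGK libraries and 2, 3 and 2 in the CAG libraries. Its level was 31.0 ± 1.03 CPM in the PGK line (n = 2) and 0.447 ± 0.131 CPM in the CAG line (n = 3), a log2 fold change of -6.06 (edgeR adjusted p = 3.67e-15). ENSG00000165379 had 86 and 65 counts in the PGK libraries and 3, 1 and 0 in the CAG libraries. Its log2 fold change was -5.90 (edgeR adjusted p = 1.26e-11). For ENSG00000165379 that size rested on few counts: it was -7.15 without CAG replicate 1 and -5.27 without CAG replicate 3, so the order of these 2 genes is not settled. The other 10 leading falls had sizes between 4.18 and 5.43 on the log2 scale.

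In the row order of the table, the fold changes were not scattered evenly but formed long stretches with a common level. The 13400 tested genes fell into 44 stretches, of which 25 lay more than 0.2 (log2) from the median of all genes. These 25 held 3815 genes (28.5%): 18 stretches with 2664 genes were shifted up in the CAG line and 7 with 1151 genes were shifted down. The shifted stretches held 21 to 524 tested genes each. Outside them 3037 genes (31.7%) were called too, and the largest shift of a stretch not counted as shifted was 0.18 in size. The row order is not described in the sources used here. Of 100 random orders of the same fold changes, 0 gave a shifted stretch. With the boundary penalty doubled, 16 stretches were shifted.

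The longest shifted stretch ran from row 17071 to row 17900 and held 524 tested genes, of which 393 were called higher and 5 lower in the CAG line. Its median shift was 0.61 on the log2 scale, a 1.52-fold rise. Rows 3319 to 3916 held 449 tested genes with a median shift of 0.39, 325 of them called higher. Rows 4616 to 5094 held 324 tested genes with a shift of 0.45. The opposite direction was seen over rows 16456 to 17070, directly before the longest stretch, where 434 tested genes had a median shift of -0.41 and 275 were called lower. Over rows 7 to 393, the shift was -0.62 in 244 tested genes, of which 195 were called lower and 1 higher. The lowest level was -1.04 over rows 1991 to 2061, in 21 tested genes. The highest was 0.85 over rows 5096 to 5146, where all 29 tested genes lay on the same side.

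**Figure D2:**
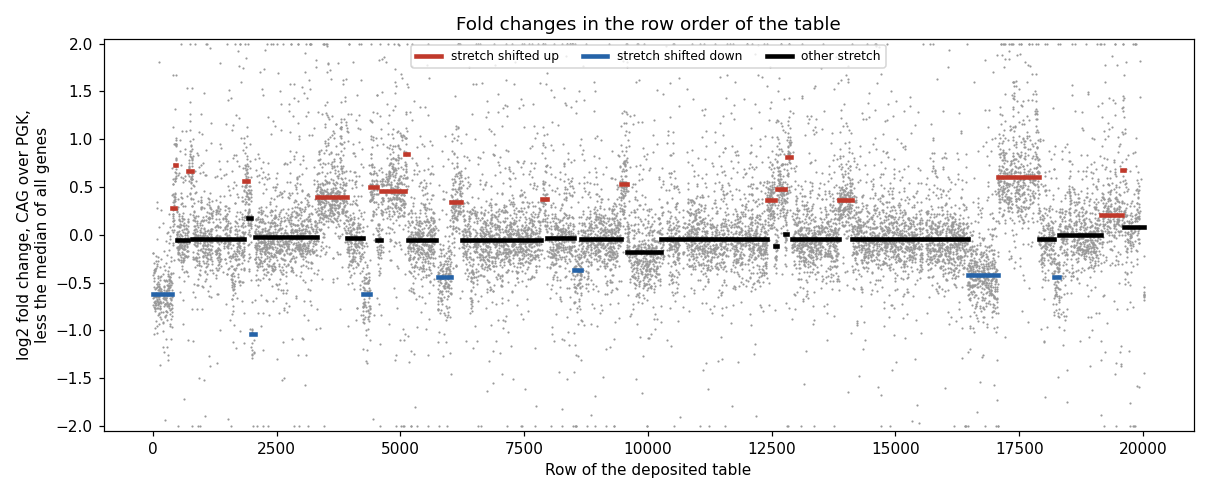
Grey points are the log2 fold changes of the 13400 tested genes, CAG over PGK, less their median, against the row of the deposited table; points beyond a size of 2 are drawn at 2. Bars mark the 44 stretches at their median, with 18 shifted up in red, 7 shifted down in blue and the others in black within 0.2 of 0.

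The share of genes on the side of their stretch ranged from 80.8% to 100% in shifted stretches, which were chosen on the same fold changes, and from 50.0% to 77.8% in the others. The levels of the 3 CAG libraries and the 2 PGK libraries did not overlap in the 25 shifted stretches, which were chosen on these same libraries, and also not in 13 of the 19 other stretches. In shifted stretches the smallest difference between the line means was 0.22 on the log2 scale, and the SD of a stretch's level within a line had a median of 0.03 in each line and a maximum of 0.12. In the longest stretch, the level relative to the mean of the 5 libraries was -0.35 ± 0.11 in the PGK line (SD, n = 2) and 0.24 ± 0.03 in the CAG line (SD, n = 3). When stretches were found from CAG replicate 1 and PGK replicate 1 alone, 25 were shifted. All 25 were shifted by more than 0.2 in the same direction in the libraries left out, where 74.1% to 100% of their genes lay on that side (median 91.4%). The shifts in the 2 sets of libraries had a Pearson correlation of 0.987 across these stretches. Only stretches shifted by more than 0.2 entered it, and the gap this leaves between rises and falls raises such a value.

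**Figure D3:**
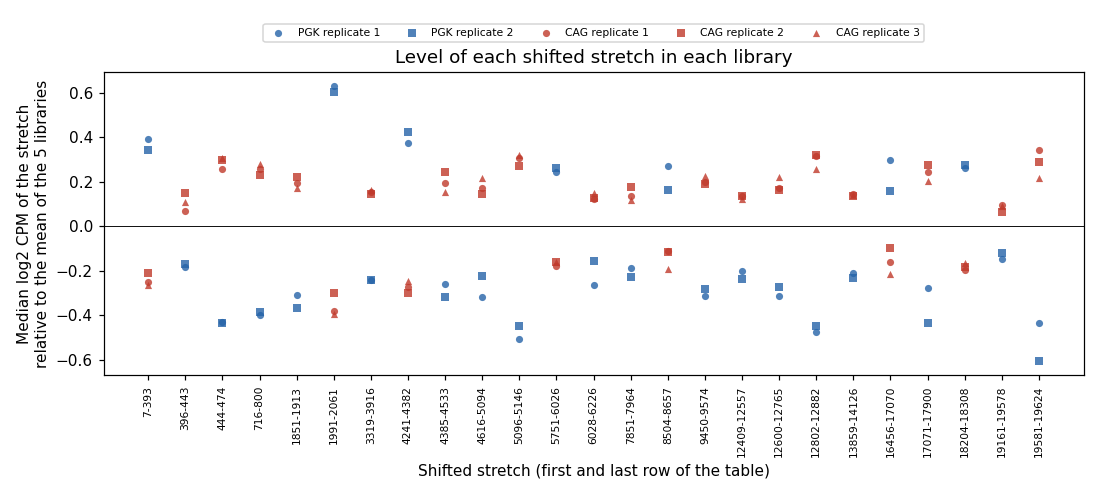
Each column is 1 of the 25 shifted stretches, named by its first and last row, and each point is 1 library's median log2 CPM of the stretch relative to the mean of the 5 libraries (blue, PGK line; red, CAG line). In every column the CAG points lie on one side of both PGK points.

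Of the 5818 called genes, 2781 (47.8%) lay in shifted stretches. There 72.9% of tested genes were called, against 31.7% elsewhere, a difference that follows in part from choosing the stretches on the same fold changes. After each stretch's median was taken out, edgeR called 3309 genes, 1641 higher and 1668 lower. Of these, 2817 had been called in the same direction before. The 2 genes with the largest falls lay outside the shifted stretches, as did ENSG00000170627, whereas ENSG00000127399 lay in a stretch shifted by 0.37. Of the 12 leading rises, 7 lay in shifted stretches, and of the 12 leading falls, 2 did.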

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

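A few counts lay in data that the comparisons did not use. The 18 rows without a gene identifier held 95 counts over the 5 libraries, at most 0.000448% of a library. They held 25 and 13 counts in the PGK libraries and 21, 15 and 21 in the CAG libraries. No test for a library standing apart was run, because no line had 4 libraries.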

How the results depend on the processing

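Thinning, the smaller library sizes, DESeq2 on the genes tested by edgeR, the removal of stretch levels and every alternative for the stretches were chosen after seeing the data. Of the alternatives fixed before the data were examined, all kept the count of 5818 genes within 1.5 times except glmTreat against 0.5, which tested a stricter hypothesis and gave 1145 genes (714 higher, 431 lower). DESeq2 on 17286 genes gave 3943 (2099 higher against 3046, 1844 lower against 2772), and on the 13400 genes tested by edgeR 4054 (2201 higher, 1853 lower), so the filter was not the main reason; the cause was not tested further. The others ran from 5524 genes (at least 1 CPM in every library) to 6024 (no filter), apart from the replicate block below. Leaving out 1 library gave 4754 to 5689 genes; where this left 1 PGK library, it was assumed to vary like the CAG libraries. Upper-quartile factors raised the share of calls that were higher from 52.4% to 56.1%, and leaving out PGK replicate 1 lowered it to 49.4%. With the replicate number as a block, 4667 genes were called, 4559 of them called in the same direction without it. The labels do not say that numbers mark a shared batch, and deviations of same-numbered libraries correlated at 0.04 and -0.07, so the numbers were not taken to pair the libraries. The 4 named genes kept their direction and an adjusted p under 0.05 in all 64 results under the 16 alternatives that tested them. At a minimum of 1 CPM in every library they were not tested. The sizes of the 2 falls moved between settings. The log2 fold change ran from -6.29 to -5.23 for ENSG00000185070 and from -7.15 to -4.78 for ENSG00000165379, in both smallest in size under limma-trend.

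Thinning all libraries to 3712105 counts gave 5236 genes, and leaving the 10 highest genes out of the library sizes gave 5818. Taking out stretch levels gave 3309 genes (1641 higher, 1668 lower), fewer because shared shifts no longer counted. The 25 shifted stretches became 16 with the penalty doubled, which allows fewer boundaries by construction, and 21 to 27 under the other settings. The share of counts in the 10 highest genes was lower in the CAG line (CAG minus PGK -0.130 percentage points), with a difference of -0.186 to -0.0574 with 1 library left out and smallest without CAG replicate 1. A share of the counts left after those genes are taken out has no meaning for the genes themselves and was not computed. Every result for gene lists, chromosomes, other gene classes, PGK1 and ACTB, was not run because identifiers were not paired with names. Depth limits scarce genes: the median standard error was 0.26 (log2) in the lowest of 4 groups of genes by level and 0.07 in the highest.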

Other observations

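The splits of the libraries and the correlation between rows were tests chosen after their results had been seen, and the other tests had bounds set before their values were seen but concern stretches, genes and settings chosen after the data had been examined.

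A small set of genes was transcribed in one line and at or under the limit of 3 counts in the other. With at least 5 CPM in one line and at most 3 counts over all libraries of the other, 11 genes were active in the CAG line and 2 in the PGK line, and edgeR called all 13. The limit of 3 counts is 0.326 CPM over the PGK libraries and 0.189 CPM over the CAG libraries, and with 0.326 CPM as the limit in both lines the numbers were 11 and 3. Their levels in the active line reached 99.1 CPM in the CAG line and 12.3 CPM in the PGK line. For 4 of the 11, the PGK libraries held 0 counts. Loss of DNA spanning neighbouring genes in the other line may be proposed for them. Of the 52 tested genes within 2 tested rows of these genes, 6 (11.5%, exact binomial 95% interval 4.35% to 23.4%) differed at least 4-fold in the same direction, against 1.55% of all tested genes that differed as much in either direction. The interval holds the bound of 20% set beforehand, so the test did not decide whether such loss lies behind some of the 13. The interval treats the 52 genes as independent and is too narrow, since fold changes 1 tested row apart correlated at 0.36. The 6 genes lay beside 5 of the 13, and the rest of the 13 had no such neighbour. This argues against loss spanning neighbouring tested genes as the cause for all 13, but not for those 5. The test assumes that neighbouring rows are neighbouring genes. Loss of a single gene and silencing in one clone were not tested.

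For the count of 5818 genes, the other 9 of the 10 splits of the libraries into 2 and 3 gave 0 genes at an adjusted p under 0.05 by edgeR, with at most 956 at an unadjusted p under 0.05, and 1 split, the real one, gave 5818 (6720 unadjusted). No other tool was run on the splits, and 10 splits are too few for a share under 0.05. Each of the other 9 splits also placed libraries of both lines in the same group. The difference between the lines then counted as spread, which makes calls unlikely, so the 0 genes do not measure what chance gives. The tables argue against the lower depth of PGK replicate 2 as the cause, since 90.0% of the count was left with every library thinned to its depth. They also argue against the shifts of the stretches found as the whole cause. Once these shifts were taken out, 3309 genes were called, which is 56.9% of the count. Of these, 2817 had been called in the same direction before. Small shared shifts that the partitioning missed were not taken out, so the values do not speak about those. What stays open, untested, is the promoter, the clone and any difference in how the lines were handled, which the design does not separate.

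For the stretches of rows with a common shift, reads shared between neighbouring or overlapping genes would reach only a few rows, yet fold changes 20 tested rows apart still correlated at 0.25, against at most 0.03 in 1000 random orders. The tables argue against library differences not tied to the line too: within a line at most 1.81% of tested genes lay in shifted stretches, against 29.1% to 32.5% in the 6 contrasts of single libraries across lines, although fold changes 20 rows apart also correlated within a line, at 0.07 in the PGK pair and at most 0.05 in the CAG pairs. A hypothesis is that the rows follow the chromosomes and that the clones differ in chromosome copy number, which would move high and low genes of a stretch alike. Its test was void: the shift differed by a median of 0.13 between the more and less abundant genes of a shifted stretch, but by 0.11 in stretches not shifted, which already exceeds the bound of 0.1 that copy number had to meet, and neither gene positions nor copy number were measured here. In most stretches, shifted or not, the less abundant genes lay further toward a rise in the CAG line than the more abundant ones. The counts of rises and falls were not corrected for this. GC content was not tested, and neither was the promoter.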
